A study of Picea glauca with 69 samples.

How the data were processed

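Total RNA of 69 untreated white spruce seedlings was reverse transcribed from 0.5 µg and amplified with SYBR Green chemistry over 40 cycles on an ABI PRISM instrument, per the labels' protocols. Seedlings were grown in a greenhouse with 16 h of light and 8 h of dark and maximum temperatures of 25 °C by day and 18 °C by night until day 92. Per the series design text families were randomized in complete blocks, but no label names a seedling's block. Per the design text equal amounts of RNA were pooled for the expression analysis, and no value was found to be set against such a pool.

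The authors deposited threshold cycles (Ct) per well, with 3 wells each for GA2ox, GA3ox, GA20ox and the control gene TIF, and 2 wells each for DELLA, GID and a second set of TIF wells. A higher Ct means less transcript. The authors also deposited a normalized sheet, which on checking holds the mean target Ct minus the mean TIF Ct of the same set of wells, a log2 value if amplification is perfect, with its sign opposite to expression. Efficiencies, threshold settings and software are not given in the sources used here. Of 345 deposited gene values, 315 were equal within 0.001 cycles to this rule and 335 to it or to a reference of all 5 TIF wells, which 4 of the last 5 samples have. The 10 others belong to 3 seedlings. In 754_OP repetition 1 the Ct values of the last well of the GA genes appear moved by 1 gene (20.3 for GA20ox against 28.9 in its other wells), and the deposited normalized values do not carry this shift. In 927*991_CC repetition 2 and 193_PM repetition 3 the values differ by at most 0.0940 cycles. In 71 of 276 sets of 3 wells the last well equalled the mean of the other 2 within 0.0001 cycles, and in 0 sets did another well do so. If these last wells were filled in, the well SDs given here are too small.

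Expression was taken as the deposited log2 value with its sign turned. No value was filtered or imputed, and no column belonged to a sample outside the series. The replicate was the family, since the breeding strategy is a property of the family: seedlings were averaged per family, and titles with 6 seedlings counted as 1 family. Some labels conflict with the titles: in 754_PM, repetitions 4 to 6 are PM by title and breeding strategy but have the sample type of a control, and they were kept as PM. Where nothing in the labels separates seed lots, p-values measure the spread between these families only.

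Contrasts between strategies were tested by exact two-sided permutation of family means (3003 splits for CC or PM against OP, 924 for CC against PM), with Benjamini-Hochberg adjustment over 15 gene contrasts and, separately, over 6 contrasts of 2 ratios, and an adjusted threshold of 0.05. Intervals of 95% were obtained by inverting the same test. Differences between families were tested by permuting seedlings over 20 families (one-sided F, 100000 resamples, adjusted over 5 genes), with limits of the intraclass correlation from 2000 bootstrap draws of families. The effect of the first-numbered tree was tested in an additive model of 18 family means with the strategy, permuting within a strategy. Correlations were tested by 100000 permutations and adjusted over 10 pairs. The gene lists were fixed before the data were examined: synthesis GA20ox and GA3ox, catabolism GA2ox, receptor GID, repressor DELLA. The rule for names was that all 5 genes appear in each comparison, with the families of highest and lowest mean for each gene, each tree's value for a contrast past the threshold, and any outlying family or seedling. Markers of other tissues were not measured.

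The tests were tried on simulated data of the same layout. With no true shift, the exact contrast test gave a p under 0.05 in 2.75% to 6.75% of 400 sets for GA2ox, GA3ox, GA20ox and GID, but in 12.8% for DELLA in CC against OP and 12.0% in PM against OP, where OP families had the smaller spread. A true shift of 0.5 was found at an unadjusted p under 0.05 in 53.8% of sets for GA3ox in CC against OP and in 37.5% in PM against OP, and a shift of 1 in 95.2% and 90.5%. For GID a shift of 0.5 was found in 100.0% of sets in CC and 97.0% in PM against OP.

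Alternatives listed before the data were examined were values recomputed from Ct, the linear scale, medians of wells, ranks, pairing by first-numbered tree, the seedling as the unit, a mixed model with a random family, the repetition number as a block, the 3 conflicting PM seedlings left out or counted as OP, OP families 96 and 154 left out, values with a well SD over 0.5 cycles left out, and each repetition and each family left out in turn. The sample-number series, sample number, TIF Ct, a reference of all TIF wells, and setting aside the well farther from the other seedlings where 2 DELLA wells differed by over 2 cycles were added after seeing the data, the last also together with TIF Ct, and so was keeping 754_OP repetition 1 among the values left out for well SD. The 5 series of sample numbers were read from where the offset between the 2 sets of TIF wells changes, not from any label. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and, for the mixed model, R 4.3.3 with lme4 1.1.37 and lmerTest 3.1.3.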

Results

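Transcript levels of 5 genes of the gibberellin pathway were measured by real-time quantitative PCR in 69 second-year seedlings of white spruce (Picea glauca), a conifer bred for growth. Per the series title the families differed in growth rate. The seedlings came from families of 3 breeding strategies: controlled crosses between 2 known parents (CC, 18 seedlings of 6 families), polymix pollination with a mixture of pollen (PM, 21 seedlings of 6 families) and open pollination, the study's control (OP, 30 seedlings of 8 families). Of the 20 families told apart by the titles, 17 had 3 seedlings and 3 had 6 (754_OP, 754_PM and 927_OP), while the design text counts 23 families of 3. The titles number the parent trees, and 6 trees numbered first, by breeding convention the seed parents, have a CC, a PM and an OP family each. The tissue is given as needles in one label and as apical internode in the extraction protocol. No seedling was treated, and harvest fell on day 92 of growth in a greenhouse.

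The genes stand for 4 steps of the pathway. GA20ox and GA3ox encode the oxidases of the last steps of synthesis of active gibberellin, GA2ox encodes an oxidase that inactivates it, GID encodes the receptor, and DELLA encodes the repressor of growth that the receptor removes when gibberellin is bound. Values are log2 expression relative to the control gene TIF, so that a difference of 1 is a factor of 2 if amplification is perfect, and a less negative value is a higher level. DELLA was the most abundant of the 5 transcripts relative to TIF, with a mean of -5.31 ± 0.64 (SD, n = 69 seedlings), followed by GID at -7.67 ± 0.38, GA20ox at -8.32 ± 0.62, GA2ox at -8.66 ± 0.73 and GA3ox at -10.22 ± 1.20, an order that compares different primer pairs. GA3ox spanned the widest range among seedlings, a factor of 48.1 from lowest to highest, and GID the narrowest, a factor of 3.93.

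The first comparison asked whether families bred by controlled cross or polymix differed from open-pollinated families in gibberellin transcripts. GA3ox had a mean of -9.93 ± 0.41 (SD, n = 6 families) in CC and of -10.50 ± 0.48 (n = 8) in OP families, a difference of 0.57 ± 0.24 (SE) or 1.48-fold (95% interval 1.02 to 2.14). PM families had GA3ox at -9.99 ± 0.53 (n = 6), 1.42-fold the OP level (95% interval 0.943 to 2.14). GID had a mean of -7.53 ± 0.16 (n = 8) in OP families. CC families had it at -7.72 ± 0.07 (n = 6, 0.875 of the OP level) and PM families at -7.81 ± 0.27 (n = 6, 0.823 of the OP level). GA2ox was -8.51 ± 0.35 in OP, -8.81 ± 0.37 in CC and -8.79 ± 0.23 in PM families, which put CC at 0.808 and PM at 0.823 of the OP level. GA20ox had means of -8.25 ± 0.44 in CC, -8.30 ± 0.23 in PM and -8.38 ± 0.33 in OP families. DELLA had means of -5.20 ± 0.45 in CC, -5.38 ± 0.46 in PM and -5.34 ± 0.08 in OP families as deposited, which include 3 CC or PM seedlings whose 2 DELLA wells differed by over 2 cycles. With the well nearer to the other seedlings, DELLA in PM minus OP moved from -0.05 to -0.21 (exact p = 0.0263, adjusted 0.151). Without values whose wells had an SD over 0.5 it was -0.26 (exact p = 0.0193, adjusted 0.206). With the family spreads as deposited, the exact test gave a p under 0.05 for this contrast in 12.0% of simulated sets with no true shift.

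**Figure D1:**
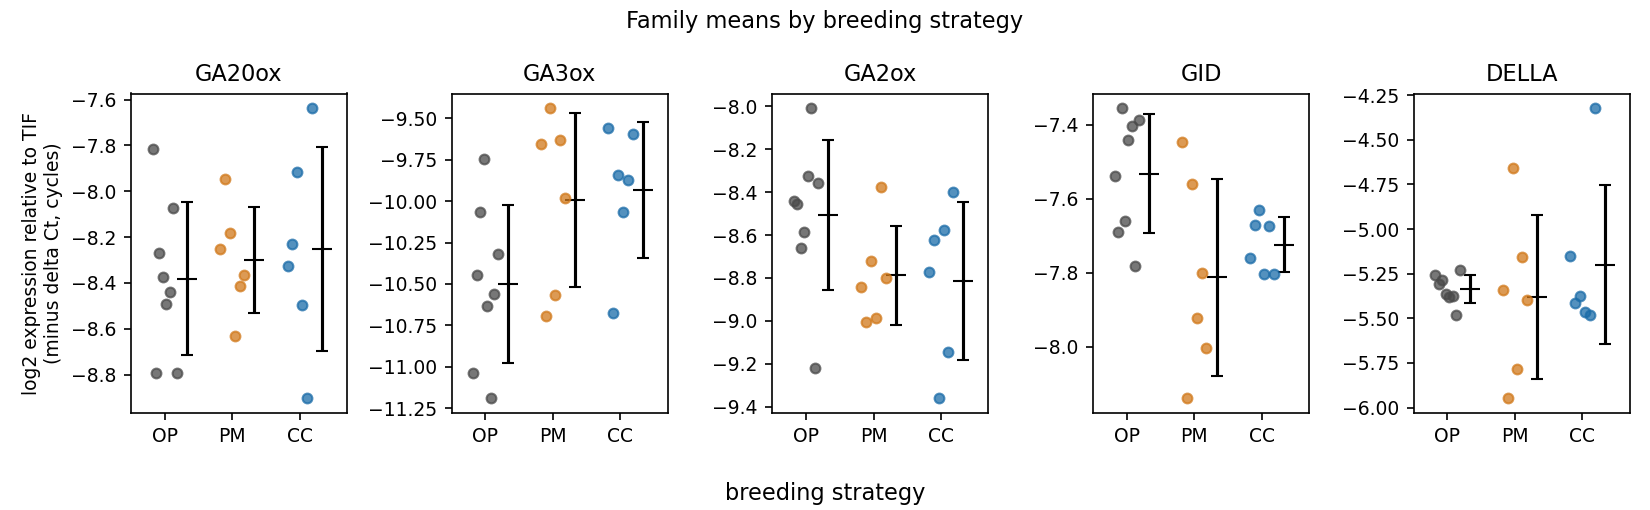
Family means of log2 expression relative to TIF (vertical axes, in cycles, each panel with its own range) for the 5 genes in open-pollinated (OP, n = 8), polymix (PM, n = 6) and controlled-cross (CC, n = 6) families; each point is 1 family and the bar beside it is the mean ± SD of families. GA3ox means lay at -10.50 in OP against -9.99 in PM and -9.93 in CC, and GID means at -7.53 in OP against -7.81 and -7.72, while the families of the 3 strategies overlapped for every gene.

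None of these differences held after correction. Of the 15 gene contrasts tested by exact two-sided permutation of family means, 0 had a Benjamini-Hochberg adjusted p under 0.05 and 3 had an unadjusted p under 0.05. The 3 were GID in CC against OP (exact p = 0.0243, adjusted 0.201), GID in PM against OP (exact p = 0.0316, adjusted 0.201) and GA3ox in CC against OP (exact p = 0.0403, adjusted 0.201). GA3ox in PM against OP had an exact p of 0.0872 (adjusted 0.327). With families paired by the 6 first-numbered trees, 0 of the 15 had an unadjusted p under 0.05: GID had an exact p of 0.0625 in CC and in PM against OP and GA3ox of 0.0938 in both, where the smallest possible is 0.0312. GA2ox had an exact p of 0.136 in CC and 0.116 in PM against OP (both adjusted 0.340). CC and PM families did not differ detectably in any gene, with exact p from 0.437 to 0.905. The intervals allowed CC to lie between 0.676 and 1.58 of PM for GA3ox and between 0.883 and 1.26 for GID. Repetitions 1 to 3 had mean sample numbers in the titles of 14.95, 33.15 and 50, so leaving one out also shifts the sample numbers kept. Without repetition 1, 0 of the 15 contrasts had an unadjusted exact p under 0.05: GID in CC minus OP moved from -0.19 to -0.05 (exact p = 0.609), GA3ox in PM minus OP from 0.51 to 0.14 (exact p = 0.731) and GA2ox in CC minus OP from -0.31 to -0.15 (exact p = 0.554). Without repetition 2, GA3ox in PM minus OP was 0.82 (exact p = 0.00566, adjusted 0.0849) and GA2ox in PM minus OP -0.53 (exact p = 0.0137), while without repetition 3 GA2ox was -0.59 in CC minus OP (exact p = 0.0157) and -0.16 in PM minus OP (exact p = 0.467). With the 3 PM seedlings of control sample type counted as OP, GID was -0.15 in CC minus OP (exact p = 0.100) and -0.22 in PM minus OP (exact p = 0.0887).

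The sample numbers in the titles fall into 5 series that differ in the Ct offset between the 2 sets of TIF wells, from 0.55 cycles in samples 33 to 56 to -0.72 in samples 25 to 32. The contrasts were set out within them. In samples 1 to 24 and 33 to 56, the 2 series with at least 5 seedlings of each strategy, GA3ox in CC minus OP was 0.30 and 1.59, GA3ox in PM minus OP 0.85 and 1.61, GID in CC minus OP -0.17 and -0.09, and GID in PM minus OP -0.40 and -0.05. The other 3 series held 1 to 5 seedlings of a strategy each. In them GA3ox in PM minus OP had the opposite sign, at -0.70 in samples 25 to 32, -0.98 in 57 to 64 and -0.27 in 65 to 69. In samples 65 to 69, with 1 OP seedling, GA3ox in CC minus OP was -0.13, and the GID differences also had the opposite sign, 0.39 in CC and 0.26 in PM. The Ct of the TIF wells run with GID was lower by family means in CC than in OP, at -0.32 cycles (exact p = 0.110), and in PM than in OP, at -0.20 (exact p = 0.490). With the mean of all 5 TIF wells as the reference, GID in CC minus OP was -0.06 (exact p = 0.446) and in PM minus OP -0.12 (exact p = 0.383).

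The second comparison used 2 ratios within each seedling, from which the control gene cancels. The ratio of synthesis to catabolism, the mean of GA20ox and GA3ox minus GA2ox, was -0.28 ± 0.47 (SD, n = 6 families) in CC, -0.36 ± 0.24 (n = 6) in PM and -0.93 ± 0.55 (n = 8) in OP families. It was 1.57-fold the OP ratio in CC (95% interval 1.03 to 2.42) and 1.49-fold in PM (95% interval 1.04 to 2.14), each with an exact permutation p of 0.0356 and an adjusted p of 0.0733 over the 6 ratio contrasts. The ratio of receptor to repressor, GID minus DELLA, was -2.52 ± 0.49 in CC, -2.43 ± 0.33 in PM and -2.20 ± 0.13 in OP families, or 0.797 of the OP ratio in CC (exact p = 0.0366, adjusted 0.0733) and 0.850 in PM (exact p = 0.0922, adjusted 0.138). CC and PM differed by 0.08 in the first ratio and -0.09 in the second, with exact p of 0.751 and 0.742. Of the 6 exact tests 0 passed the adjusted threshold and 3 had an unadjusted p under 0.05. The ratio contrasts were not tried on simulated data. GID over DELLA had a family SD of 0.49 in CC against 0.13 in OP. A like imbalance gave DELLA in CC against OP a p under 0.05 in 12.8% of simulated sets with no true shift. The unadjusted count was 0 of 6 by ranks of family means and 0 of 6 with families paired by tree, where the 3 contrasts each had an exact p of 0.0625. On the linear scale it was 1 of 6, with synthesis to catabolism at an exact p of 0.0849 in CC and 0.0836 in PM against OP.

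**Figure D2:**
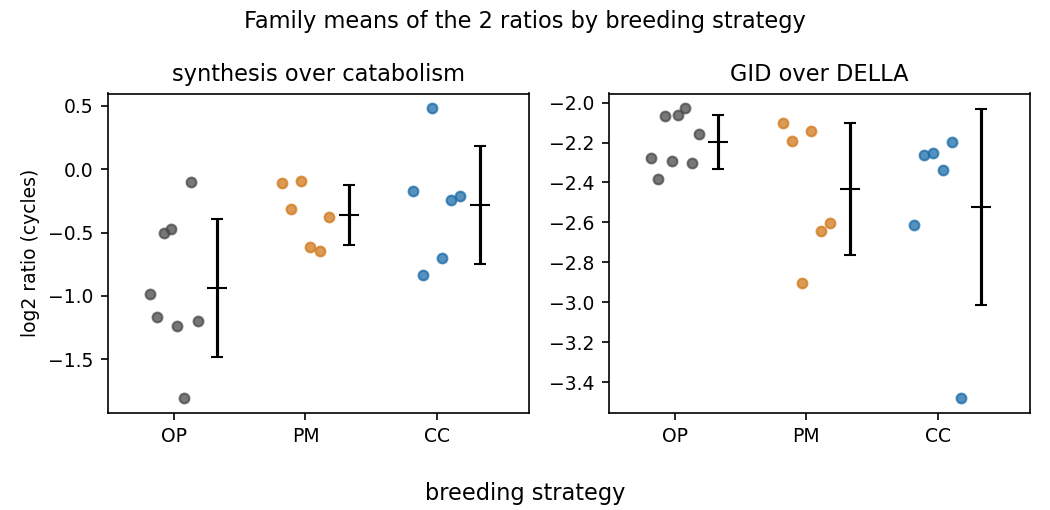
Family means of the log2 ratio of gibberellin synthesis genes to GA2ox (left) and of GID to DELLA (right), vertical axes in cycles, by breeding strategy; each point is 1 family and the bar is the mean ± SD of 8 OP, 6 PM and 6 CC families. The synthesis to catabolism ratio averaged -0.93 in OP, -0.36 in PM and -0.28 in CC families, and the lowest point of the right panel, -3.48, is family 927*991_CC.

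Within samples 1 to 24 and 33 to 56 the synthesis to catabolism ratio in CC minus OP was 0.36 and 0.96, and in PM minus OP 0.32 and 1.45. In the 3 smaller series PM minus OP was negative, at -0.25 in samples 25 to 32, -0.16 in 57 to 64 and -0.50 in 65 to 69, and CC minus OP was 0.93, 1.04 and -0.999. GID over DELLA in CC minus OP was -0.02 in samples 1 to 24 and -0.25 in 33 to 56, and -0.29, -0.33 and -1.65 in the 3 smaller series, the last of which holds the seedling of 927*991_CC with discordant DELLA wells. In PM minus OP it was -0.17 and -0.63 in the 2 larger series, and 0.30, -0.19 and -0.16 in the smaller ones. The value of -0.63 includes 754_PM repetition 2 and 138_PM repetition 3, whose DELLA wells were also discordant. The synthesis to catabolism ratio of CC minus OP passed the adjusted threshold without repetition 3 (1.00, exact adjusted p = 0.00599), that of PM minus OP without repetition 2 (0.93, exact adjusted p = 0.0380), and both without family 927_OP (0.77 and 0.70, exact adjusted p = 0.0367). Without 754_OP they were 0.53 and 0.45 (exact p = 0.0606 and 0.0530), without 193_OP 0.61 and 0.53 (exact p = 0.0600 and 0.0565) and without 96_OP 0.62 and 0.54 (exact p = 0.0589 and 0.0559), and each of these left 0 of the 6 ratio contrasts with an unadjusted p under 0.05. Without repetition 1 the differences were 0.43 and 0.34 (exact p = 0.252 and 0.333). The seedlings of 927_OP, except sample 61, lie in samples 1 to 24, where this ratio averaged -0.06 against -0.90 in 33 to 56. Leaving this family out therefore also shifts the sample numbers of the OP seedlings kept. Without values whose wells had an SD over 0.5, the CC minus OP difference was 0.50 (exact p = 0.146) and the PM minus OP difference 0.56 (exact p = 0.0180, adjusted 0.108), and with 754_OP repetition 1 kept they were 0.51 (exact p = 0.139) and 0.57 (exact p = 0.0180). When the deviating DELLA well was set aside in each of 3 seedlings, GID over DELLA in CC minus OP moved from -0.33 to -0.15 (exact p = 0.0733) and in PM minus OP from -0.23 to -0.07 (exact p = 0.465).

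The third comparison asked whether seedlings of a family resembled each other more than seedlings of different families. They did not do so detectably for any of the 5 genes. The SD between seedlings of the same family was 0.74 for GA2ox, 1.26 for GA3ox, 0.63 for GA20ox, 0.66 for DELLA and 0.38 for GID, against SDs between family means of 0.34, 0.52, 0.33, 0.34 and 0.21 for the same genes. Means of 3 to 6 seedlings spread less than single seedlings even with no family effect, so these SDs alone do not answer the question. The intraclass correlation, the share of variance between families, was -0.04 for GA2ox, -0.11 for GA3ox, -0.04 for GA20ox, -0.05 for DELLA and 0.01 for GID. Bootstrap 95% limits over families reached at most 0.196, for GID. A one-sided permutation test of F over the 20 families gave p from 0.434 (GID) to 0.840 (GA3ox), all with an adjusted p of 0.840. Simulated data of the same layout with an intraclass correlation of 0.4 gave a p under 0.05 in 91.0% of 400 sets, and with 0.2 in 49.5%, so that a family share of 0.2 could have been missed. The simulated data held no shift between sample-number series. Mean sample numbers rose from 14.95 in repetition 1 to 50 in repetition 3. Mean GA2ox went from -9.13 in samples 1 to 24 to -8.25 in samples 33 to 56. Such a shift adds to the spread within a family and lowers the intraclass correlation.

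Family means ranged most for GA3ox, from -11.19 ± 1.15 (SD, n = 6 seedlings) in 754_OP to -9.44 ± 0.62 (n = 3) in 138_PM. The family 754_OP also had the highest GA2ox, at -8.01 ± 0.42 (n = 6), and the lowest ratio of synthesis to catabolism of all 20, -1.81 ± 0.89. In 5 of its 6 seedlings the GA3ox wells had an SD over 0.5 cycles, out of 8 such GA3ox values in the series. One of the 5 is repetition 1, whose last wells appear moved by 1 gene, so that 4 seedlings, of 7 such values, remain as spread of GA3ox wells. The seedlings of 754_OP had sample numbers 19, 39, 40, 51, 57 and 63. Those of 927_OP, with GA2ox at -9.22 and a ratio of -0.10, had 2, 3, 7, 23, 24 and 61. GA2ox and the ratio differed between the sample-number series, so both family means may carry part of that difference. In samples 1 to 24, 754_OP repetition 1 had GA2ox at -7.96. The family 138*752_CC had the lowest GA2ox, at -9.36 ± 1.05 (n = 3), with the highest ratio, 0.48 ± 1.04. GA20ox lay between -8.90 ± 0.63 in 754*966_CC and -7.64 ± 0.19 in 927*991_CC (n = 3 each). DELLA and GID were both lowest in 129_PM, at -5.95 ± 0.41 and -8.14 ± 0.31 (n = 3). GID was highest in 138_OP, at -7.35 ± 0.12, and DELLA in 927*991_CC, at -4.32 ± 1.83 (n = 3 each), where a single seedling with 2 discordant wells set the mean.

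The fourth comparison took the 18 families of the 6 trees with all 3 strategies and asked whether families of the same first-numbered tree were alike after the strategy was taken into account. Of the 5 genes GID had the smallest p, with means over 3 families from -7.86 ± 0.12 (SD) for tree 927 to -7.52 ± 0.14 for tree 138, and a permutation p of 0.0659 (one-sided, F = 2.56, adjusted 0.329 over 5 genes). With the sample-number series as a fixed term its F was 1.17 (permutation p = 0.389), and without repetition 1 it was 1.13 (permutation p = 0.417). The ratio of synthesis to catabolism, not among the tests fixed in advance, had an F of 3.12 (permutation p = 0.0510, adjusted 0.102 over the 2 ratios) and, with the series as a fixed term, an unadjusted permutation p of 0.0464. GA20ox had a permutation p of 0.241, GA3ox of 0.285, DELLA of 0.533 and GA2ox of 0.833, with adjusted p from 0.474 to 0.833. Without repetition 1 GA20ox had the smallest p, with its F at 4.65 against 1.62 (permutation p = 0.0104, adjusted 0.0519). In simulated data in which trees varied as much as the residual, 54.2% of 400 sets gave a p under 0.05.

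The fifth comparison asked which genes varied together over the 20 family means. GA3ox and DELLA had the strongest relation, with Pearson's r of 0.52 (permutation p = 0.0150, adjusted 0.150 over 10 pairs) and Spearman's rho of 0.56 (permutation p = 0.0116, adjusted 0.116). Without the 2 families farthest from the median of GA3ox r was 0.65, past the threshold (permutation p = 0.00074, adjusted 0.0074), and with the sample-number series as a fixed term it was 0.40 (permutation p = 0.0807). With the 3 discordant DELLA wells set aside, over all 20 families, it was 0.25 (permutation p = 0.288). GA2ox and GID had r of 0.42 (permutation p = 0.0692) and rho of 0.37 (permutation p = 0.114). GA2ox and DELLA had r of 0.37 (permutation p = 0.112) and rho of 0.50 (permutation p = 0.0273). DELLA and GID had r of 0.28 as deposited (permutation p = 0.231, rho 0.36) and 0.64 with the 3 wells set aside (permutation p = 0.00203, adjusted 0.0203). Of the 10 pairs 0 passed the adjusted threshold by Pearson or by Spearman correlation as deposited, with 1 pair at an unadjusted permutation p under 0.05 by Pearson and 2 by Spearman.

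GA2ox was higher in seedlings with a higher sample number in the titles. Its level had r of 0.51 with the number over 69 seedlings (permutation p = 2.0e-05, adjusted 0.00014 over the 5 genes and 2 ratios), rho of 0.48 (permutation p = 3.0e-05) and r of 0.51 without the 2 farthest samples. The mean was -9.13 ± 0.70 (SD, n = 24) in samples 1 to 24, -9.01 ± 0.57 (n = 8) in 25 to 32, -8.25 ± 0.63 (n = 24) in 33 to 56, -8.44 ± 0.37 (n = 8) in 57 to 64 and -8.22 ± 0.43 (n = 5) in 65 to 69. Within these series r was 0.13 (permutation p = 0.294). The permutations over all 69 seedlings take them as exchangeable between the series. If the series are runs or blocks, the p-values for GA2ox and the ratio over all seedlings are too small. From samples 1 to 24 to samples 33 to 56 the mean Ct of GA2ox went from 29.4 to 29.6 cycles and that of its TIF wells from 20.3 to 21.3, while GA3ox Ct went from 30.3 to 31.3 and GA20ox Ct from 28.4 to 29.7. The other 4 genes had r from -0.09 to 0.17, with permutation p from 0.153 to 0.930. The ratio of synthesis to catabolism, which contains GA2ox, fell with sample number, with r of -0.39 (permutation p = 0.0011, adjusted 0.00385), rho of -0.38 (permutation p = 0.00133), r of -0.38 without the 2 farthest samples and r of 0.07 within the series (permutation p = 0.560). Its mean was -0.06 ± 0.94 (SD, n = 24) in samples 1 to 24 and -0.90 ± 0.98 (n = 24) in 33 to 56. GID over DELLA had r of -0.17 (permutation p = 0.167).

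**Figure D3:**
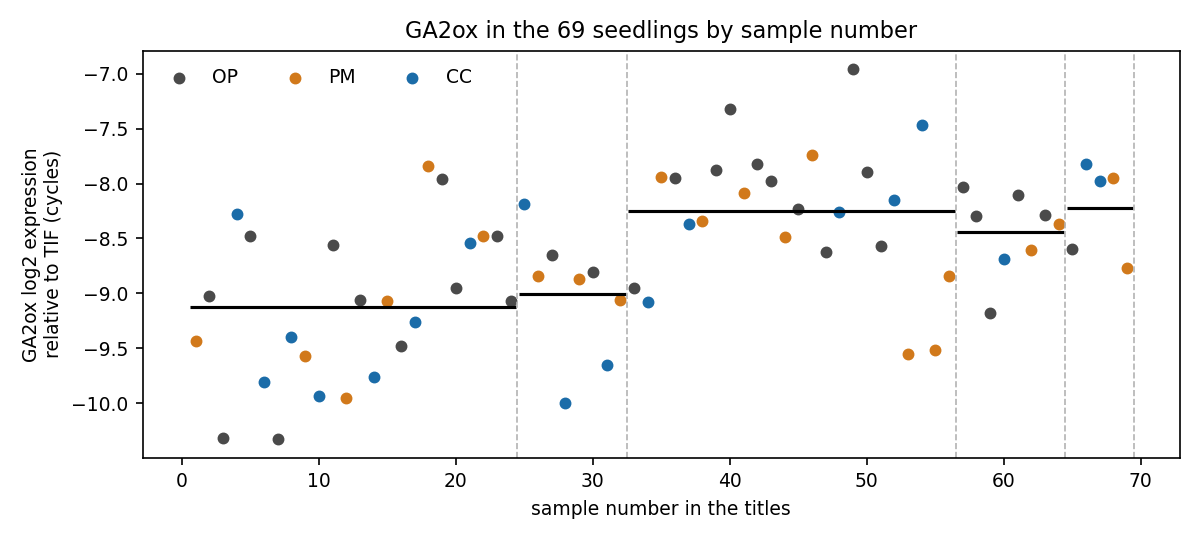
GA2ox log2 expression relative to TIF (vertical axis, in cycles) against the sample number in the titles (horizontal axis) for 69 seedlings coloured by breeding strategy; dashed lines separate the 5 series of sample numbers and horizontal bars are their means. Means went from -9.13 in samples 1 to 24 to -8.25 in samples 33 to 56.

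Repeat wells of a seedling measured pipetting and amplification, and not the error of RNA extraction, reverse transcription or run. The pooled SD of wells of the same seedling was 0.22 cycles for GA2ox, 0.29 for GA3ox, 0.63 for GA20ox, 0.73 for DELLA, 0.23 for GID, and 0.10 and 0.16 for the 2 sets of TIF wells. In 18 values the wells had an SD over 0.5, of which 8 were of GA3ox and 3 belong to the moved wells of 754_OP repetition 1. Without them the pooled SD was 0.18 for GA2ox, 0.19 for GA3ox, GA20ox and GID, and 0.16 for DELLA. Mean Ct was 31.2 for GA3ox, the latest to amplify, and 21.0 and 21.2 for the TIF wells.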

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

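In 42 sets of 6 to 8 values (the seedlings of each larger family, and the family means of each strategy, for 5 genes and 2 ratios), 3 values lay far from the others, where chance gives about 2.1. All 3 involve DELLA. In 754_PM, repetition 2 had DELLA at -4.09, with its gap to the nearest seedling 0.682 of the range of 6. The family 927*991_CC had a DELLA mean of -4.32 and a GID to DELLA ratio of -3.48, with gaps of 0.714 and 0.676 of the range of the 6 CC families.

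In both families the high DELLA came with discordant wells. The DELLA wells read 24.6 and 27.0 cycles in 754_PM repetition 2 and 20.9 and 27.3 cycles in 927*991_CC repetition 3, and 138_PM repetition 3 had 23.0 and 27.7. The well closer to the other seedlings gave -5.29, -5.41 and -4.98 in these 3 seedlings, inside the range of the other 66 seedlings, which ran from -6.58 to -4.60, while the other well gave -2.89, 0.97 and -0.26, all above it. The nearer well was picked for lying closer to the median of those 66 seedlings. Its place inside their range therefore does not show which well is right. No explanation of the discordant wells was tested.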

How the results depend on the processing

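The repetition numbers were not taken to pair seedlings. Of 570 comparisons between families within a repetition number, 44.9% had deviations that correlated above 0.1, with a median of 0.01. Each correlation rests on the few measures of a seedling, so this does not show that the repetitions are unpaired. Deviations of GA2ox from family means still differed by repetition, at -0.31, -0.03 and 0.34 in repetitions 1 to 3 (permutation p = 0.00299, adjusted 0.0209 over 7 measures), and those of synthesis over catabolism were 0.38, -0.07 and -0.31 (permutation p = 0.0214, adjusted 0.0748). Mean sample numbers were 14.95, 33.15 and 50 in these repetitions, so the differences cannot be told apart from the trends with sample number. The series, sample number, TIF Ct, all-TIF reference and DELLA well settings were chosen after seeing the data. The family tests (55 values over the 11 alternatives run) and first-tree tests of genes (40 values over 8) stayed above the threshold, and no gene contrast passed it under the alternatives run. The first-tree test was run on the linear scale, on recomputed values, without the control-type PM seedlings, without each repetition, with the series and with the nearer DELLA well. Unadjusted, 0 to 4 of the 15 gene contrasts and 0 to 4 of the 6 ratio contrasts had a p under 0.05 under the alternatives. Of the contrasts, counts of calls and well SDs recomputed under alternatives, 920 values kept direction and side, 52 changed direction, 6 contrasts passed the threshold and 6 counts or SDs moved by over 1.5 times. The cause of the changes below was not tested, except that the leave-outs, the replicate block and the within-strategy values rest on fewer seedlings or families. With TIF Ct removed, 2 of 6 ratio contrasts passed, GID over DELLA CC minus OP (-0.41) and PM minus OP (-0.29), and 2 contrasts near 0 changed sign (DELLA PM minus OP 0.016, GA2ox CC minus PM 0.016). These 2 calls include the discordant DELLA wells: with TIF Ct removed and the nearer DELLA well, 0 of 6 passed, at -0.18 (exact p = 0.0300, adjusted 0.0773) and -0.091 (exact p = 0.314), and GA2ox CC minus PM was again 0.016. The replicate block used repetitions 1 to 3 only, which drops repetitions 4 to 6 of 754_OP, 754_PM and 927_OP. Each family then has 1 seedling per repetition, so the block term cannot move a difference between families. The values of this setting therefore differ through the dropped seedlings. GA3ox CC minus PM was -0.076 in it, as it was without the 3 control-type PM seedlings or with them as OP. With repetitions 1 to 3 only, 0 of 6 ratio contrasts had an unadjusted exact p under 0.05, against 3 with all seedlings. Synthesis over catabolism was 0.64 in CC minus OP (exact p = 0.113) and 0.60 in PM minus OP (exact p = 0.0996). Of the 15 gene contrasts 2 had an unadjusted exact p under 0.05, against 3 with all seedlings. No adjusted call changed. On the linear scale DELLA PM minus OP was 0.26 and GA2ox CC minus PM 0.041. With seedlings as the unit, or a mixed model, DELLA PM minus OP was 0.0046. By ranks of family means DELLA CC minus OP was -1.17 and GA2ox CC minus PM 0.33. GA2ox CC minus PM was 0.039 with the series and 0.047 with sample number removed. With all TIF wells, GA20ox CC minus OP was -0.021, GA20ox PM minus OP -0.084 and DELLA PM minus OP 0.11. Values recomputed from Ct carry the moved GA20ox well of 754_OP repetition 1, which put this OP seedling 2.85 above its deposited GA20ox. Recomputed against the own TIF set, GA20ox CC minus OP was 0.068 against 0.13 as deposited, and PM minus OP 0.017 against 0.083. The part of the moved well in the 2 GA20ox sign changes was not separated. Without values of wide well spread DELLA CC minus OP was -0.022 and PM minus OP -0.26, GA20ox CC minus PM -0.027, GID over DELLA PM minus OP 0.012, synthesis over catabolism CC minus PM -0.066, and the well SD 0.16 for DELLA and 0.19 for GA20ox. The 4 contrasts that turned in this setting had the same values with 754_OP repetition 1 kept. With the nearer DELLA well, DELLA CC minus OP was -0.042 and PM minus OP -0.21.

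Leaving out a repetition or a family in turn gave DELLA CC minus OP from -0.11 to 0.34, DELLA PM minus OP from -0.29 to 0.10, GA20ox CC minus OP from -0.0056 to 0.26, GA20ox PM minus OP from -0.030 to 0.17, GA20ox CC minus PM from -0.075 to 0.18, GA2ox CC minus OP from -0.59 to -0.15, PM minus OP from -0.53 to -0.16 and CC minus PM from -0.43 to 0.32, GA3ox CC minus OP from 0.41 to 0.71, PM minus OP from 0.14 to 0.82 and CC minus PM from -0.16 to 0.27, GID CC minus OP from -0.28 to -0.047, PM minus OP from -0.40 to -0.20 and CC minus PM from -0.013 to 0.16, GID over DELLA CC minus OP from -0.43 to -0.14, PM minus OP from -0.30 to -0.12 and CC minus PM from -0.19 to 0.10, synthesis over catabolism CC minus OP from 0.43 to 1.00, PM minus OP from 0.34 to 0.93 and CC minus PM from -0.38 to 0.55, with 0 to 2 ratio contrasts past the threshold. The leave-outs that gave calls were repetition 2, repetition 3 and 927_OP.

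Of the correlations 79 values kept direction and side, 7 passed the threshold and 24 changed direction. Those that passed were GA3ox and DELLA without the 2 farthest families (0.65, permutation adjusted p = 0.0074), centred on the other 3 genes (0.65, adjusted 0.0129) and within PM (0.93, adjusted 0.0138). DELLA and GID passed without the 2 farthest families (0.60, permutation adjusted p = 0.0398), among seedling deviations (0.34, adjusted 0.0369, permuting over all seedlings) and with the nearer DELLA well (0.64, adjusted 0.0203). GA2ox and GID passed centred on the other 3 genes (0.73, permutation adjusted p = 0.0040). Centring subtracts the same mean of 3 genes from both genes of a pair, which puts a shared term into both. The permutation breaks that term, so the centred p-values cannot test a relation between the genes themselves. The direction of r in this setting also carries the shared term. The other 24 values turned. Without the 2 farthest families GA20ox and DELLA had -0.045, GA2ox and GA20ox 0.030, GA2ox and GA3ox 0.018, GA3ox and GID 0.17. Centred on the other 3 genes GA20ox and GID had 0.33, GA2ox and GA20ox 0.21, GA3ox and GID 0.085. Among seedling deviations GA2ox and DELLA had -0.075, GA2ox and GA20ox 0.18, GA3ox and DELLA -0.097, GA3ox and GA20ox -0.082. Within PM GA2ox and GA3ox had 0.72, GA3ox and GID 0.80, GA3ox and GA20ox -0.025, GA20ox and DELLA -0.0070. Within CC DELLA and GID had -0.56, GA2ox and GID -0.81, GA2ox and GA20ox 0.28, and within OP GA20ox and DELLA -0.22, GA3ox and GA20ox -0.28. Centred on strategy GA3ox and GA20ox had -0.051 and GA3ox and GID 0.29. Recomputed, GA3ox and GA20ox had -0.090, with the moved GA20ox well of 754_OP repetition 1 in the recomputed values. The family 754_OP had the lowest GA3ox, so this well can lower that r. With the nearer DELLA well GA20ox and DELLA had -0.082. The number of wells, 2 or 3 per gene, limits the precision of each seedling's value.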

Other observations

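The tests here were chosen only after the results were seen, except 2 that were written down before their values were known: DELLA and GID with series and family removed, and DELLA against GID with no shared reference and the series left in. The 66 seedlings used for DELLA and GID were also chosen after seeing the wells.

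DELLA and GID, the repressor and the receptor of the same signal, rose and fell together among seedlings of the same family. Without the 3 seedlings with discordant DELLA wells, their deviations from family means had r of 0.74 over 66 seedlings and rho of 0.75, both with the smallest p that 100000 permutations within families can give (1.0e-05), and r was 0.76 without the 2 farthest seedlings. It was 0.68 in CC (n = 17, permutation p = 0.0227), 0.55 in PM (n = 19, permutation p = 0.0435) and 0.85 in OP (n = 30, permutation p = 2.0e-05). With all 69 seedlings as deposited r was 0.34 (p = 0.00036 by permutation within families, and 0.00369 by permutation over all seedlings). The 3 GA genes showed no such relation to each other, with r of -0.11 for GA2ox and GA3ox, 0.21 for GA2ox and GA20ox and -0.09 for GA3ox and GA20ox (permutation p from 0.179 to 0.616).

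DELLA and GID were set against the same TIF wells, so an error in those wells could move both, while the GA genes were measured in the other set of wells, whose offset differs between the sample-number series. In the test written in advance, with GID set against the mean Ct of the 3 GA genes so that no reference was shared, r fell to 0.21 (permutation p = 0.137), which leaves that explanation open. With series and family both removed, r was 0.50 with no shared reference (permutation p = 0.00056), in a test added after the one above, and 0.77 with the shared one, which argues against shared wells and against the series as the whole cause. With GID set against the other TIF wells r was 0.25 (permutation p = 0.0611), and 0.62 with series and family removed (permutation p = 1.0e-05, the smallest possible). No biological explanation was tested, since apart from the sample type in 754_PM the labels name no difference between seedlings of a family.

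CC and PM families together had a higher ratio of synthesis to catabolism than OP families, -0.32 ± 0.36 (SD, n = 12) against -0.93 ± 0.55 (n = 8), a factor of 1.53 (exact p = 0.00588, adjusted 0.0118 over the 2 ratios). Differences between the sample-number series may add to it. The difference was 0.59 with the series as a fixed term (exact p = 0.0116, which takes the fitted series terms as known). It was 0.49 without 754_OP, the OP family with the lowest ratio (exact p = 0.0176). Most of the difference thus remained in either setting. In samples 1 to 24 and 33 to 56 CC and PM both exceeded OP. In samples 25 to 32, 57 to 64 and 65 to 69 PM minus OP was -0.25, -0.16 and -0.50, and CC minus OP 0.93, 1.04 and -0.999. These permutations treat families of the same tree as independent. Leaving out each family in turn gave exact p from 0.00079 to 0.0176, but without repetition 1 the difference was 0.39 (exact p = 0.184), and without values of wide well spread 0.53 (exact p = 0.0330), or 0.54 with 754_OP repetition 1 kept (exact p = 0.0301). Within first-numbered trees the mean of CC and PM exceeded OP in 5 of 6 trees, by 0.65 on average (exact sign-flip p = 0.0625, where the smallest possible is 0.0312), with 0.85 in tree 122, 0.59 in 129, 0.70 in 138, 0.58 in 193, 1.37 in 754 and -0.20 in 927. The OP seedlings of the last 2 trees were uneven over the series, mostly in samples 33 to 64 for 754 and 1 to 24 for 927. A higher ratio in bred families stays a hypothesis, found by pooling strategies whose separate contrasts had adjusted p of 0.0733, and it rests on GA3ox and GA2ox, since GA20ox, the other synthesis gene, differed by a factor of 1.08 (exact p = 0.495). For single genes the same pooling gave GID lower by a factor of 1.18 (exact p = 0.0104, adjusted 0.0522 over 5 genes), but by 1.06 against all 5 TIF wells (exact p = 0.371), GA3ox higher by 1.45 (exact p = 0.0219, adjusted 0.0548) and GA2ox lower by 1.23 (exact p = 0.0568, adjusted 0.0946).

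The rise of GA2ox with sample number may be a step between runs or blocks, or a steady drift. The r within the series, 0.13, does not decide between them, since each series covers a short stretch of sample numbers. If the series are runs or blocks, the permutation p-values below are too small, since they take seedlings as exchangeable between the series. Deviations of GA2ox from family means had r of 0.49 with sample number (permutation p = 3.0e-05), so the family of the seedling does not account for the rise. TIF Ct also rose, from 20.3 cycles in samples 1 to 24 to 21.9 in samples 65 to 69 in the wells run with the GA genes, while GA2ox Ct was 29.4 and 30.1, but after TIF Ct was removed as a linear term GA2ox kept r of 0.42 with sample number (permutation p = 0.00041), which argues against the reference or the amount of template as the whole cause. Whether the rise is technical, or a difference between greenhouse blocks or harvest times of the seedlings, cannot be read from the labels.

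Raw Ct of GA2ox and DELLA rose by 0.70 and 0.71 cycles per cycle of TIF Ct, against 0.92 to 0.95 for GA3ox, GA20ox and GID. In 754_PM, the 3 seedlings with the sample type of a control had GA3ox at -10.45 ± 2.07 (SD, n = 3) and the other 3 at -8.81 ± 1.19, with an exact p of 0.40, where 3 against 3 cannot go below 0.10.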
